A study of Homo sapiens with 32 samples.

How the data were processed

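Total RNA of MCF7 cells, an established estrogen receptor-positive breast cancer line, was biotin-labelled and hybridised to exon arrays, which carry probesets for single exons of most human genes. Per the labels, cells grown in 10% fetal bovine serum were moved to phenol red-free medium with 2% charcoal-stripped serum for 3 days before treatment with 10 nM 17β-estradiol or 0.1% ethanol for 6 or 24 hours. The 32 deposited samples are 16 arrays given at 2 levels, gene (transcript cluster) and exon (probeset). When each level's arrays were centred on their mean, each of the 16 gene-level columns correlated best with the exon-level column of the same name (r from 0.855 to 0.938 over 11284 genes).

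The deposited values are log2 expression values. The scale was read from the values, since the log base is not stated by the labels. How the authors corrected the background, summarised the probes and normalized the arrays is not given in the sources used here. Array medians differed, from 6.36 to 6.65 at the gene level, so that the deposited values were not quantile-normalized after summarisation. Any intensity differences between arrays that remained would enter each comparison, and for that reason quantile normalization and median centring were run as alternatives. The genome build hg18 is named in the submitters' processing notes. No coordinates are given here, since the reference annotation used for names is on another build.

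Names came from the platform annotation, updated through gene identifiers and synonyms. At the gene level 14432 transcript clusters had 1 symbol, 2408 had several and 5171 had none; at the exon level 261273 probesets had 1, 9155 several and 16901 none. Genes are named only from features with 1 symbol. For 209 genes with several clusters, gene lists and fixed genes used the cluster with the highest mean level. Of the genes named here ABHD2, SLC1A5, BIRC5 and FN1 had 2 clusters: the dimmer ones had log2 changes of 0.50 in SLC1A5 at 6 hours (adjusted p = 0.309), 0.47 in BIRC5 at 24 hours (adjusted p = 0.0492), -0.45 in FN1 at 24 hours (adjusted p = 0.261) and 1.45 in ABHD2 at 6 hours (adjusted p = 0.000354), the ABHD2 cluster named among the largest rises.

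Gene-level values were tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table version 1.17.8), with a mean per group over all 16 arrays, no filter and no covariate, two-sided, with Benjamini-Hochberg adjustment over 22011 clusters and a threshold of 0.05. The contrasts were estradiol against control at each time, the difference between these effects, and the 24 against the 6 hour controls. Gene lists, 24 in number and written from general knowledge before the data were examined, were tested with camera at its preset correlation of 0.01, with the correlation estimated from the data as an alternative, and with fry, which tests whether a list moves on balance one way. They covered estrogen-induced and estrogen-repressed genes, cell cycle, ribosome, metabolic, stress and signalling genes, and markers of other cell types. Changes are given with SE from the fit and levels with SD.

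Exon-level values were tested with limma's diffSplice on probesets above the 25th percentile of mean level, with 1 symbol, in genes with at least 4 such probesets. The test of where in the gene the called probesets lie, planned for the case that positions were given, was not run, because no probeset positions were at hand.

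Genes were named by a rule fixed before the data were examined. For estradiol against control at each time, these were the 10 largest rises and 10 largest falls among called clusters whose groups did not overlap, and for the other gene-level contrasts the 5 largest called in each direction. TFF1, GREB1, PGR, ESR1, MYC, CCND1, CXCL12 and ERBB2 were named whatever their values. At the exon level the rule took the 5 largest relative changes in each direction among called probesets whose groups did not overlap, 1 per gene. For list members the fixed rule had set a higher limit and did not ask for a call. Here up to 3 called members of each list were chosen, and other called members are named in places.

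The gene, list and probeset tests of estradiol against control were tested on simulated data built from each feature's mean over all arrays and its spread within groups. The difference between times, the controls and fry were not simulated. At the gene level, estradiol against control at 6 hours, 97.5% of 40 simulated log2 changes of 2 were recovered, 73.8% of 80 changes of 1 and 20% of 80 changes of 0.5, with 13 calls among 21811 unchanged clusters. At 24 hours the shares were 90%, 78.8% and 20%, with 7 such calls. Camera recovered the 1 shifted list and called 0 of 23 others at each time. The simulated genes were drawn independently, however, while correlations estimated in the data reached 0.587 within a list. The simulation therefore says nothing of false calls by camera on correlated genes. diffSplice, which uses one variance for all probesets of a gene, recovered 98% and 100% of 100 relative changes of 2 at 6 and 24 hours, but called 561 and 569 of the 192116 other probesets, some of which share a gene with a changed one. On simulated arrays without any changed probeset, added after seeing the data, it called 428 and 417 of 192316 probesets, and the test with each probeset's own variance called 0 and 0. That test was itself added after seeing the data, and beside the simulated changes it called 5 and 6 other probesets while recovering 86% and 82% of the changes of 2 and 16% and 12% of those of 1. The simulated probesets were drawn independently too, so that their calls do not give the number of false calls in the data.

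Alternatives tried were a replicate block, quantile normalization, median centring, leaving out the dimmest 30% of clusters, a robust intensity trend, array weights, the arrays of 1 time point alone, a 1.5-fold minimum, leaving out each array in turn, and for probesets other level filters and a splicing index against the gene-level value. Whether the replicate numbers pair the samples is not stated, and the block was run only as an alternative. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).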

Results

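MCF7 is a line of estrogen receptor-positive human breast cancer cells whose growth responds to estrogens. The cells were kept for 3 days in medium without phenol red and with 2% charcoal-stripped serum, which removes most steroid hormones, and then received either 10 nM 17β-estradiol or 0.1% ethanol, its solvent. RNA was taken after 6 or 24 hours and labelled for exon arrays. There were 4 groups of 4 samples: control and estradiol at 6 hours, and control and estradiol at 24 hours. Each of the 16 arrays was deposited both as 22011 gene-level values (transcript clusters) and as 287329 exon-level values (probesets). Values were on a log2 scale, with array medians from 6.36 to 6.65 at the gene level and from 6.56 to 6.97 at the exon level. The number of arrays, 4 per group, limited the precision. The labels do not say whether the replicates came from separate cultures, so that p-values measure only the spread between these samples.

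The first comparison asked which genes responded to estradiol within 6 hours. Estradiol raised CXCL12, a chemokine, from a log2 level of 6.18 ± 0.48 in the controls to 8.01 ± 0.25 (SD, n = 4 each), and PGR, the progesterone receptor, from 7.45 ± 0.45 to 9.24 ± 0.31. NPY1R, a neuropeptide Y receptor, rose from 8.06 ± 0.78 to 9.73 ± 0.30, and GREB1, an estrogen-induced cofactor of the estrogen receptor, from 9.17 ± 0.37 to 10.61 ± 0.12. The interleukin-1 receptor gene IL1R1 fell from 7.03 ± 0.44 to 5.41 ± 0.16, and the growth factor gene TGFB3 from 8.08 ± 0.33 to 6.96 ± 0.13. In all, 214 of 22011 transcript clusters changed (limma, Benjamini-Hochberg adjusted p under 0.05), 171 of them higher and 43 lower with estradiol.

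The other large rises at 6 hours were in the cytokine receptor gene IL17RB (log2 change 1.60 ± 0.18, SE), the placenta-enriched PLAC1 (1.59 ± 0.20), and the tyrosine kinase gene FRK (1.47 ± 0.22). Next came the hydrolase gene ABHD2 (1.45 ± 0.16), RAPGEFL1 (1.45 ± 0.15) and the small GTPase gene RAB31 (1.43 ± 0.13). A brighter transcript cluster of ABHD2 rose by 0.60, and PLAC1 was dim in the controls, at 4.66, below the lower quartile of each array, so that the size of its rise is uncertain. Among the falls were the lactate receptor gene HCAR1 (-1.36 ± 0.20), the secretory GTPase gene RAB27B (-1.09 ± 0.16) and the endocytic adaptor gene DAB2 (-1.07 ± 0.22, to a dim 4.42). Further falls were in the epithelial transcription factor gene GRHL3 (-1.06 ± 0.15), the cell cycle kinase gene CDK6 (-0.97 ± 0.15), the actin-binding LIMA1 (-0.97 ± 0.16), the mitochondrial thiolase gene ACAA2 (-0.95 ± 0.17) and RNF144B (-0.94 ± 0.19). Values of the 4 estradiol and 4 control arrays did not overlap for 211 of the 214 called clusters, and for 5.05% of all clusters, where chance gives 2.86%.

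Of the 8 genes fixed for description whatever their values, CCND1, which encodes cyclin D1, rose by 0.50 ± 0.10 at 6 hours (adjusted p = 0.0314, limma), beside GREB1, PGR and CXCL12. The classical estrogen target TFF1 had a log2 change of 0.56 ± 0.18 on a high level of 12.33 ± 0.39 in the controls, and did not pass (adjusted p = 0.225). MYC at 0.65 ± 0.16 (adjusted p = 0.0696), ERBB2 at -0.54 ± 0.13 (adjusted p = 0.0646) and ESR1, the estrogen receptor itself, at -0.37 ± 0.11 (adjusted p = 0.192) did not pass either. Under 16 alternative settings fixed beforehand MYC newly passed in 4, ERBB2 in 3 and ESR1 in 1.

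**Figure D1:**
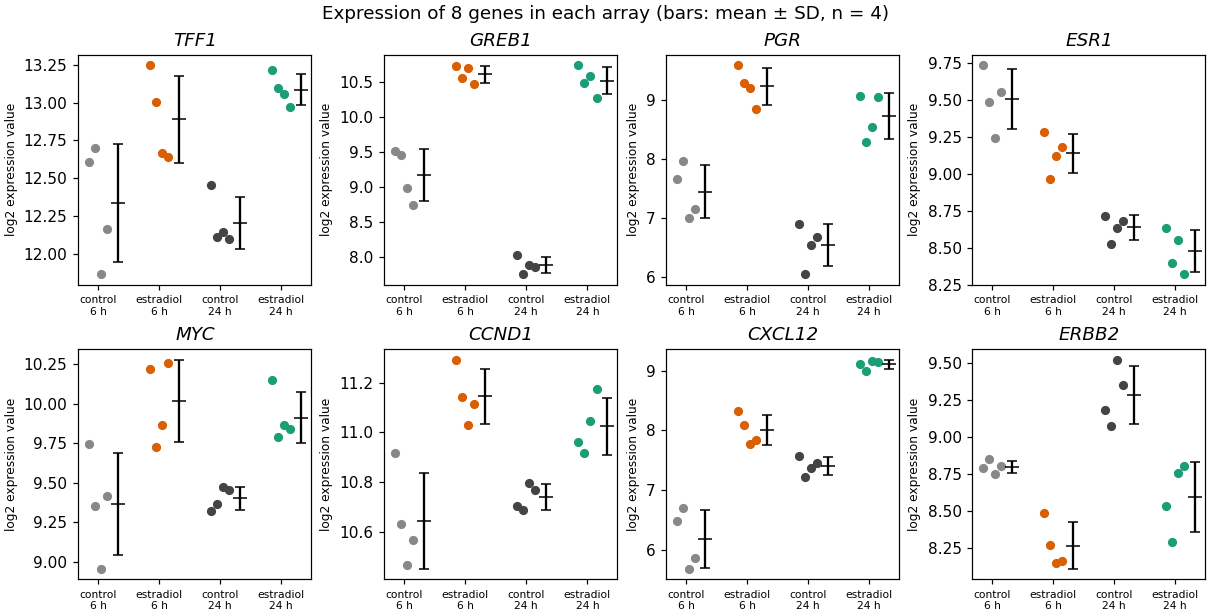
Log2 expression value (vertical axis) of 8 genes in each of the 16 arrays, by group (horizontal axis), with dots for arrays and bars for the mean ± SD of 4 arrays. GREB1 averaged 9.17 and 10.61 in the control and estradiol arrays at 6 hours, and 7.88 and 10.52 at 24 hours.

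Gene groups fixed before the data were examined showed which functions moved at 6 hours. Of 41 measured estrogen-induced genes 23 rose and 0 fell, among them RET, a receptor tyrosine kinase gene (1.40 ± 0.10), RAB31 (1.43 ± 0.13) and the carbonic anhydrase gene CA12 (1.36 ± 0.14). Adjusted over the list alone, 33 rose. Of 33 estrogen-repressed genes 7 fell and 0 rose, among them IL1R1 (-1.62 ± 0.20), TGFB3 (-1.12 ± 0.15) and BMF, a pro-apoptotic gene (-0.70 ± 0.11). Adjusted over the list alone, 12 fell and 1 rose. Of 51 genes of the G1/S transition and DNA replication 12 rose and 0 fell, such as the replication licensing gene CDC6 (1.17 ± 0.21), UHRF1 (0.92 ± 0.16) and MCM10 (0.91 ± 0.14), and 38 rose when adjusted over the list alone. Of 31 ribosome biogenesis genes 4 rose and 0 fell, with NOLC1 (0.91 ± 0.13), DDX21 (0.80 ± 0.12) and RRP12 (0.57 ± 0.09), and 23 rose when adjusted over the list alone. These 4 lists were shifted as sets by camera (adjusted p = 1.61e-51, 3.08e-17, 2.27e-36 and 4.29e-20), and stayed so with an estimated correlation (adjusted p = 0.00729, 0.00729, 0.0469 and 0.0469).

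Of 24 genes of amino acid supply and ATF4 targets 4 rose and 0 fell, including the amino acid transporter genes SLC7A5 (1.12 ± 0.14), SLC1A5 (0.70 ± 0.14) and SLC1A4 (0.51 ± 0.09), and 10 rose when adjusted over the list alone. Of 22 TGF-beta and SMAD targets 1 fell, TGFB3, and 0 rose, both over all genes and adjusted over the list alone. Camera called the first list up and the second down, but with an estimated correlation the adjusted p = 0.102 for each. By fry the adjusted p = 0.00936 and 0.0514. The other lists that camera called at 6 hours had 0 members past the test. G2/M and mitosis genes had a median change of 0.17, unfolded protein response genes 0.10 and reference genes 0.19, all called up, while interferon-stimulated genes at -0.07 and NF-kB targets at -0.03 were called down. With an estimated correlation their adjusted p = 0.626, 0.626, 0.451, 0.626 and 0.298, in that order.

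Camera called none of the other 13 lists at 6 hours. Growth factors and receptor kinases had 3 of 31 members higher (RET, CXCL12 and IGFBP4), textbook alternative-promoter genes 4 higher (PGR, GREB1, BRCA1 and CCND1) and 1 lower (TGFB3) of 26, and nuclear receptors and coregulators 2 higher of 23 (PGR and NRIP1). Of 23 immediate early genes EGR3 alone was higher (1.39), and of 22 apoptosis regulators BMF alone was lower. In the lists for cholesterol synthesis, p53 targets, hypoxia, aryl hydrocarbon receptor targets, and luminal, basal, mesenchymal and leucocyte markers, 0 members passed.

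At 6 hours the count was 323 with array weights, 26 with only the 8 arrays of that time, 121 and 94 without control replicates 3 and 4, and 119 and 83 without estradiol replicates 1 and 2. Without both arrays numbered 3, a setting chosen after seeing the data, it was 100. After quantile normalization of the deposited values 300 clusters changed, 199 higher and 101 lower, so that the share of rises was 66.3% against 79.9% as deposited. Leaving out single arrays ended the calls of CCND1 in 6 of 8 fits, of NPY1R, DAB2, RNF144B and SLC1A5 in 5, of ACAA2 in 3, of SLC1A4 in 2 and of CDC6 in 1, and without control replicate 3 camera called 7 lists in place of 11. With only the 8 arrays of that time all of these genes lost their calls, and so did PLAC1, HCAR1, TGFB3, RAB27B, CDK6, LIMA1, BMF, MCM10, UHRF1, DDX21, RRP12, SLC7A5 and IGFBP4. With arrays centred on their medians CCND1 did not pass.

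At 24 hours the same question covered a later response. GREB1 stood at 10.52 ± 0.19 with estradiol against 7.88 ± 0.11 in the controls (SD, n = 4 each), a difference of 6.24-fold. NPY1R was at 9.24 ± 0.56 against 6.81 ± 0.38 and PGR at 8.74 ± 0.39 against 6.54 ± 0.36. MME, which encodes the surface peptidase neprilysin, fell from 7.20 ± 0.35 to 5.12 ± 0.32, and IL1R1 from 7.56 ± 0.28 to 5.72 ± 0.25. In all, 1072 of 22011 transcript clusters changed (limma, adjusted p under 0.05), 388 higher and 684 lower with estradiol.

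Other large rises at 24 hours were in the mitochondrial carrier gene SFXN2 (2.12 ± 0.21, SE), the keratin gene KRT13 (1.89 ± 0.29), TMEM164 (1.87 ± 0.18), the lysosomal galactosidase gene GLA (1.87 ± 0.18), ARHGAP36 (1.76 ± 0.14), the transcriptional repressor gene HEY2 (1.76 ± 0.17) and CXCL12 (1.70 ± 0.19). Other large falls were in the membrane protein gene TM4SF1 (-1.69 ± 0.31), the lysine-degrading enzyme gene AASS (-1.65 ± 0.35) and the GABA receptor subunit gene GABBR2 (-1.64 ± 0.27). ARHGAP36 had a control level of 4.28, below the lower quartile of each array, so that the size of its rise is uncertain. DAB2 fell too (-1.57 ± 0.22), with the actin-binding caldesmon gene CALD1 (-1.56 ± 0.23), the netrin gene NTN4 (-1.55 ± 0.24), the hypoxia-inducible factor gene EPAS1 (-1.51 ± 0.25) and ACAA2 (-1.47 ± 0.17). The groups did not overlap for 970 of the called clusters, and for 11.8% of all clusters.

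Among the fixed genes TFF1 rose by 0.89 ± 0.18 at 24 hours (adjusted p = 0.00829, limma) and ERBB2 fell by 0.69 (SE 0.13, adjusted p = 0.0047). MYC at 0.51 ± 0.16 (adjusted p = 0.0789), CCND1 at 0.29 ± 0.10 (adjusted p = 0.14) and ESR1 at -0.16 ± 0.11 (adjusted p = 0.441) did not pass. Under 16 alternative settings fixed beforehand MYC newly passed in 4 and CCND1 in 1.

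Cell cycle genes made up a large group at 24 hours. Of the 51 G1/S and DNA replication genes 39 rose and 0 fell, among them the replication factor genes CDC45 (1.69 ± 0.14) and MCM10 and the transcription factor gene E2F1 (0.83 ± 0.09), and 47 rose when adjusted over the list alone. Of the 39 G2/M and mitosis genes 19 rose and 0 fell, with MYBL2 (1.60 ± 0.19), FOXM1 (1.11 ± 0.12) and the chromosomal passenger gene BIRC5 (1.11 ± 0.13), and 34 rose when adjusted over the list alone. Of the estrogen-induced genes 28 rose and 0 fell, with CA12 at 1.49 ± 0.14 and TMPRSS3 at 1.35 ± 0.12 from a dim 4.81, and of the estrogen-repressed genes 15 fell and 0 rose, with RASD1 at -1.38 ± 0.11. Adjusted over the list alone the counts were 34 and 22. Of the TGF-beta and SMAD targets 12 fell and 0 rose, including CCN2 (-1.22 ± 0.14), TGFBI (-1.19 ± 0.19) and TGFB3 (-1.07 ± 0.15), and 17 fell when adjusted over the list alone. These 5 shifts held with an estimated correlation (adjusted p = 0.0136, 0.0352, 0.0108, 0.0108 and 0.0108, in the order given).

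Stress and signalling lists were called lower by camera at 24 hours, but with an estimated correlation none of these calls held. Of 23 immediate early genes 4 fell and 1 rose, EGR1 (-0.96 ± 0.14), DUSP1 (-0.73 ± 0.13), JUN (-0.72 ± 0.10) and JUNB (-0.75) against EGR3, at an adjusted p = 0.175 with an estimated correlation. Of 23 p53 targets and cell cycle inhibitors 3 fell and 0 rose, TP53INP1 (-1.17 ± 0.22), CDKN2B (-0.75 ± 0.14) and PLK2 (-0.69 ± 0.17), at an adjusted p = 0.19 with an estimated correlation. Among 22 apoptosis regulators 5 fell, the pro-apoptotic BIK (-0.84 ± 0.12), BMF (-0.82 ± 0.11), BAK1 (-0.87) and CASP9 (-0.54) and the survival gene BCL2L1 (-0.37), and 1 rose, the survival gene BCL2 (0.86 ± 0.18), with an adjusted p = 0.192 by an estimated correlation. For interferon-stimulated genes 1 of 29 rose, XAF1 (0.93 ± 0.18), and 1 fell, IRF1 (-0.56 ± 0.15), which was also 1 of the 2 NF-kB targets that fell, beside ICAM1 (-0.46 ± 0.13). Aryl hydrocarbon receptor targets had 1 of 5 lower, AHR itself (-0.96 ± 0.16). The adjusted p = 0.489, 0.214 and 0.214 for these 3 lists with an estimated correlation. Fry tests only whether a list moves on balance one way. It called the immediate early, p53, apoptosis, NF-kB and aryl hydrocarbon receptor lists lower (adjusted p = 0.00205, 0.00302, 0.00302, 0.00457 and 0.00816), but not the interferon list (0.106). Adjusted over the list alone, 9, 8, 7, 6, 5 and 3 members fell, in the order of this paragraph. There 1 member rose in each of the immediate early, apoptosis and interferon lists.

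Camera called amino acid supply up with 1 member higher, SLC7A5 (0.86 ± 0.14), ribosome biogenesis up with 0 of 31 members past the test, and the alternative-promoter genes up with 4 higher (PGR, GREB1, TFF1 and BRCA1) and 3 lower (ERBB2, TGFB3 and BCL2L1). BRCA1 rose by 1.34 ± 0.17. With an estimated correlation these 3 had an adjusted p = 0.551, 0.551 and 0.192, and by fry 0.398, 0.432 and 0.00457. The remaining lists were not called. Growth factors and receptor kinases had 4 higher, CXCL12, GFRA1 (0.87), RET (0.97 ± 0.10) and IGFBP4 (0.87 ± 0.15), and 6 lower. Nuclear receptors and coregulators had 2 higher, PGR and NRIP1 (0.85 ± 0.15), and 2 lower, NCOA7 (-0.75) and PPARG (-0.85 ± 0.16). Hypoxia targets had 1 higher, ALDOC (0.61 ± 0.14), and 3 lower, DDIT4 (-0.69), EGLN3 (-0.80 ± 0.16) and HILPDA (-0.75 ± 0.16). Luminal markers had 2 lower (CLDN4, -0.83, and KRT7, -0.31), basal markers 2 lower (CDH3, -0.55, and EGFR, -0.47), mesenchymal markers 1 lower (SNAI2, -1.20) and cholesterol synthesis 1 higher (EBP, 0.73). The unfolded protein response list had XBP1 higher (0.90) and PPP1R15A lower (-0.46), and of leucocyte markers and reference genes 0 passed by limma, over all genes and adjusted over the list alone. The mean and median of the mesenchymal list were -0.07 and 0.11, and those of the unfolded protein response list were -0.04 and -0.07 beside an upward camera direction.

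**Figure D2:**
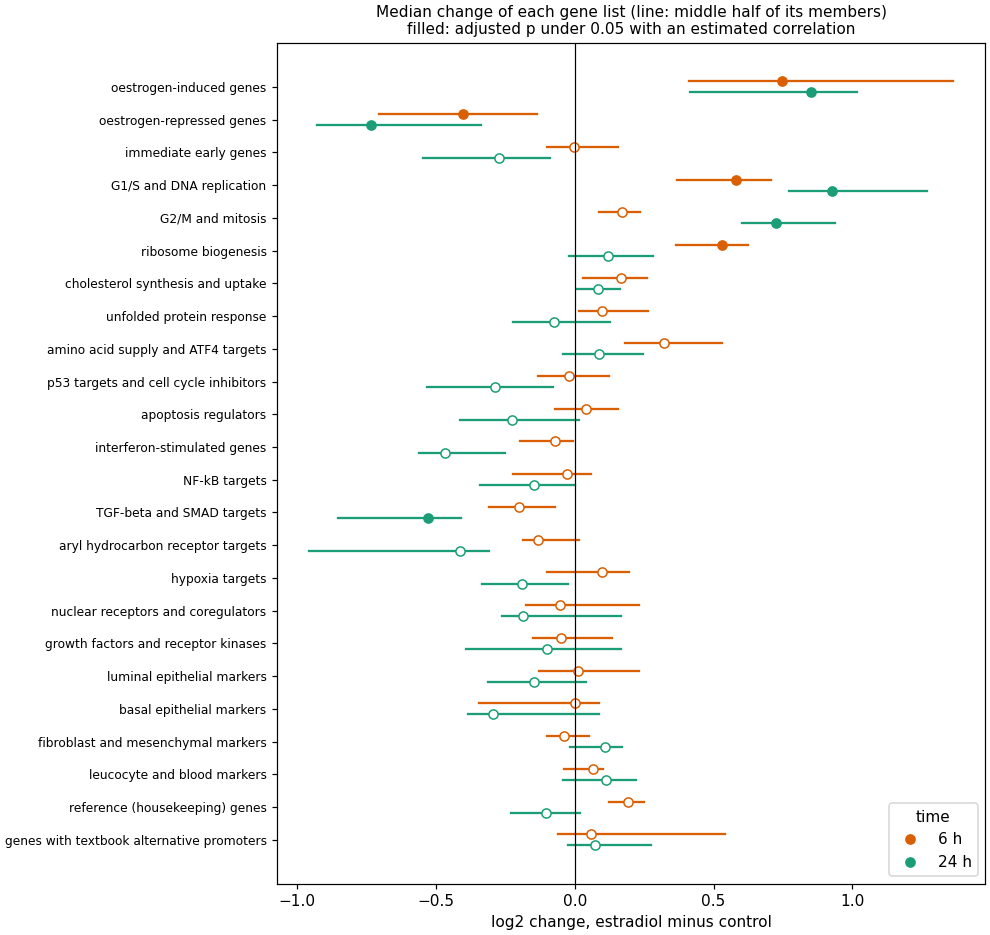
Median log2 change (horizontal axis) of each fixed gene list (vertical axis) at 6 and 24 hours, with a line over the interquartile range of its members; filled points mark an adjusted p under 0.05 with an estimated correlation. The G1/S list moved from a median of 0.58 at 6 hours to 0.93 at 24 hours, and the G2/M list from 0.17 to 0.73.

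The split between rises and falls depended on scaling: after quantile normalization 1160 clusters changed, 601 higher and 559 lower, so that rises made up 51.8% against 36.2%, and with arrays centred on their medians 592 were higher and 612 lower. Array weights gave 4280 clusters, leaving out estradiol replicate 1 gave 2384, and leaving out control replicate 1, 3 or 4 or estradiol replicate 2 or 3 gave 635, 592, 647, 589 and 638. ICAM1, IRF1 and PLK2 were each lost in 6 of the 8 fits without 1 array, and AASS and ALDOC in 1. With only the 8 arrays of that time ICAM1, IRF1, PLK2 and BCL2 did not pass while MYC did, and after quantile normalization ICAM1 and IRF1 did not pass.

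Both times were then set side by side to ask whether the early response persisted. Of the 214 clusters called at 6 hours, 203 had the same sign at 24 hours and 73 of these were larger at 24 hours. Choosing clusters by their call at 6 hours favours large changes at that time, so that the 73 do not show whether the response faded. Both times called 85 clusters higher, GREB1, PGR, NPY1R and CXCL12 among them, where independent lists would share 3.01, and 35 lower, IL1R1 and TGFB3 among them, where 1.34 would be shared. The tropomyosin gene TPM1 rose at 6 hours (0.62) and fell at 24 hours (-0.36), the only cluster called in opposite directions. Across all 22011 clusters, which are not independent replicates, the log2 changes correlated weakly (Pearson r = 0.179, Spearman rho = 0.0752; r = 0.349 without the dimmest 30% of clusters), and no control array was shared between the times.

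**Figure D3:**
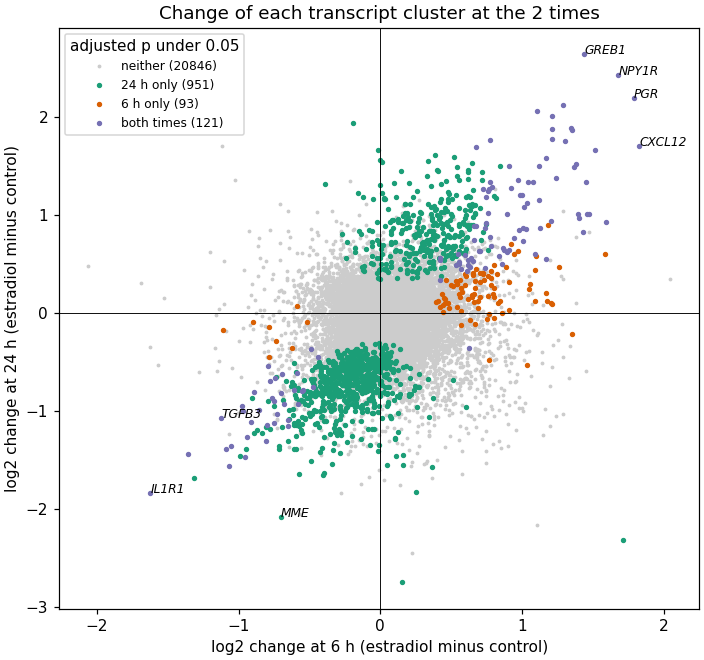
Log2 change with estradiol at 6 hours (horizontal axis) against that at 24 hours (vertical axis) for each of 22011 transcript clusters, coloured by the time at which its adjusted p was under 0.05. GREB1 changed by 1.44 and 2.64, and IL1R1 by -1.62 and -1.84.

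The difference between the 2 estradiol effects was tested gene by gene. A pair of histone genes gained at 24 but not at 6 hours: H2BC14 was at 11.48 ± 0.23 and 11.46 ± 0.26 in control and estradiol arrays at 6 hours (SD, n = 4 each), and at 10.33 ± 0.19 and 11.99 ± 0.24 at 24 hours. H1-4, a linker histone gene, went from 10.27 ± 0.14 in the 24 hour controls to 11.45 ± 0.11 with estradiol, against 10.96 ± 0.19 and 10.84 ± 0.14 at 6 hours. The dehydrogenase gene DHRS2 also had a larger estradiol effect at 24 hours, by 0.93 ± 0.14. In the other direction TIAM1, an activator of the GTPase RAC, was at 6.82 ± 0.07 and 7.91 ± 0.03 in control and estradiol arrays at 6 hours and at 7.28 ± 0.17 and 7.40 ± 0.13 at 24 hours.

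TPM1 (-0.98 ± 0.14) and the spermine oxidase gene SMOX (-0.77 ± 0.12) had lower effects at 24 than at 6 hours. These 6 were all the genes called (adjusted p from 0.0161 to 0.0355, limma), 3 in each direction, while 2502 clusters had an unadjusted p under 0.05. GREB1, whose effect was 1.20 ± 0.22 larger at 24 hours, did not pass (adjusted p = 0.109), and neither did any other fixed gene. In 4 of 23 alternative settings the GREB1 difference passed. PGR differed by 0.41 ± 0.35, TFF1 by 0.33 ± 0.25, ESR1 by 0.21 ± 0.16, CXCL12 by -0.12 ± 0.27, MYC by -0.14 ± 0.22, ERBB2 by -0.16 ± 0.18 and CCND1 by -0.22 ± 0.15. Quantile normalization moved the median of all clusters from -0.08 to 0.03 and gave 43 calls, 36 higher and 7 lower, while median centring gave 25, with 21 higher. The count was 0 without control 24 hour replicate 4 or estradiol 24 hour replicate 3, 1, 2 and 3 without estradiol 6 hour replicates 1, 3 and 4, 25 without estradiol 24 hour replicate 1, and 15 with array weights. Of the 16 fits without 1 array, SMOX was lost in 14, DHRS2 in 11, TIAM1 in 5, TPM1 in 4, H2BC14 in 3 and H1-4 in 2. No list member passed over all genes by limma, and although camera called lists in both directions, such as G2/M genes up (median 0.59, 17 higher adjusted over the list alone), none held with an estimated correlation (the lowest adjusted p = 0.198).

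Control samples differed between the times as well, which gives the background to both effects. The labels name no batch shared by both times. In comparisons of 24 with 6 hour samples, a change over time therefore cannot be told apart from a batch. From 6 to 24 hours without estradiol, VTCN1, an immune checkpoint ligand gene, rose from 5.95 ± 0.48 to 9.01 ± 0.16 and ACTG2, a smooth muscle actin gene, from 7.11 ± 0.39 to 10.05 ± 0.24 (SD, n = 4 each). CALD1 rose from 4.81 ± 0.33 to 7.69 ± 0.26, AASS from 6.27 ± 0.74 to 8.92 ± 0.30 and the flippase gene ATP10D from 5.15 ± 0.31 to 7.66 ± 0.21. The kallikrein gene KLK11 fell from 7.75 ± 0.71 to 6.10 ± 0.32 and the microseminoprotein gene MSMB from 6.21 ± 0.61 to 4.58 ± 0.32. The lower levels of CALD1 and MSMB were below the lower quartile of the arrays of their group. Some genes that estradiol raised at 24 hours were lower in the 24 hour than in the 6 hour controls, HEY2 by -1.35 ± 0.17 (SE), GREB1 by -1.29 ± 0.16, NPY1R by -1.24 ± 0.34 and PGR by -0.90 ± 0.25, while CXCL12 rose by 1.22 ± 0.19. ESR1 fell by 0.87 (SE 0.11) and ERBB2 rose by 0.48 ± 0.13, but after quantile normalization ERBB2 stood at 0.22 and did not pass (adjusted p = 0.323). TFF1 at -0.13 ± 0.18, CCND1 at 0.09 ± 0.10 and MYC at 0.03 ± 0.16 did not pass, and the last pair had the other sign after quantile normalization (-0.09 and -0.22).

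In all, 2337 clusters differed between the control groups (limma, adjusted p under 0.05), 2166 higher and 171 lower at 24 hours. Of 29 interferon-stimulated genes 24 were higher and 0 lower at 24 hours, such as the antiviral GTPase gene MX1 (2.01 ± 0.22), IFIT5 (1.40 ± 0.19) and IFITM1 (1.07 ± 0.17). Camera called the list up, and so did fry (adjusted p = 0.000205), but by camera with an estimated correlation the adjusted p = 0.243. Of the estrogen-repressed genes 13 rose, with EPAS1 (2.32 ± 0.25) and RASD1 (1.97 ± 0.11), and 1 fell, the mucin gene MUC1 (-0.73), whereas 13 estrogen-induced genes fell and 3 rose, CXCL12, FHL2 (0.64) and SLC7A5 (0.79). TGF-beta and SMAD targets had 11 higher and 0 lower, with PMEPA1 (1.43 ± 0.19), TGFBR2 (1.41 ± 0.18) and CCN2 (1.36 ± 0.14). Amino acid supply genes had 9 higher, led by the cystine transporter gene SLC7A11 (2.48 ± 0.21), and 1 lower, STC2 (-0.80). G2/M genes had 8 lower and 0 higher, with AURKB (-0.78 ± 0.15), MKI67 (-0.65 ± 0.14) and UBE2C (-0.56 ± 0.11).

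Camera called none of the lists of mesenchymal, basal, luminal and leucocyte markers between the controls. Mesenchymal markers had 4 of 18 higher, with SNAI2 (1.67 ± 0.24), CDH2 (1.41 ± 0.24) and FN1 (1.40 ± 0.26), basal markers 3 of 8, CAV1 (1.59 ± 0.25), CDH3 (0.54 ± 0.15) and EGFR (0.48 ± 0.13), and leucocyte markers 0 of 11 by limma, both over all genes and adjusted over the list alone. Ribosome biogenesis had 8 higher, immediate early genes 7, apoptosis regulators 7, p53 targets 5, NF-kB targets 5, hypoxia targets 4, reference genes 3 (B2M, TFRC and IPO8), cholesterol synthesis 1 (SC5D) and aryl hydrocarbon receptor targets 1 (AHR), each with 0 lower. Growth factors had 8 higher and 3 lower, nuclear receptors 4 higher and 2 lower, alternative-promoter genes 2 higher and 3 lower, the unfolded protein response 2 higher and 1 lower (XBP1), luminal markers 1 higher and 2 lower, and G1/S genes 1 lower (GINS1). After quantile normalization the medians of the lists with only rises shrank: p53 targets from 0.23 to -0.01, apoptosis regulators from 0.36 to 0.11, hypoxia from 0.30 to 0.12, ribosome biogenesis from 0.33 to 0.16, NF-kB from 0.24 to 0.11 and reference genes from 0.43 to 0.22. Immediate early genes went from 0.34 to 0.07. Camera then no longer called the immediate early, p53, hypoxia and reference lists (adjusted p = 0.0636, 0.329, 0.122 and 0.139). These lists were tested between the controls only after seeing the data, and with an estimated correlation none held (the lowest adjusted p = 0.243).

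**Figure D4:**
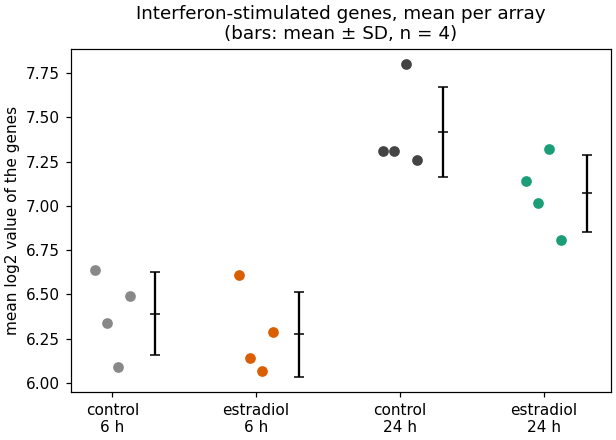
Mean log2 value of 29 interferon-stimulated genes (vertical axis) in each array (dots) of the 4 groups (horizontal axis), with bars for the mean ± SD of 4 arrays. The 8 arrays at 6 hours lie between 6.07 and 6.64, and the 8 arrays at 24 hours between 6.81 and 7.80.

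For the controls, quantile normalization moved the median of all clusters from 0.10 to -0.04 and the count to 1131, with 766 higher and 365 lower, so that rises made up 67.7% against 92.7%; median centring gave 1302, with 965 higher. Without control 6 hour replicate 1 or 3 the count was 1301 and 1158, without control 24 hour replicate 1, 3 or 4 it was 1198, 921 and 1240, and 1381 clusters changed by at least 1.5-fold. The groups did not overlap for 2140 of the called clusters and for 17.8% of all clusters. Of the 8 fits without 1 array, the calls of NPY1R, CDH3 and GINS1 between the controls were lost in 6, of PGR, EGFR, IPO8 and TFRC in 5, of ERBB2 in 4, of MUC1 in 3 and of B2M in 2. After quantile normalization CDH3, EGFR, B2M, TFRC and IPO8 did not pass either.

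The series concerns alternative promoters under estrogen, which would show as some exons of a gene changing otherwise than the rest. The neprilysin gene MME gave such a profile at 24 hours: 19 of its 23 tested probesets had log2 changes of -1.58 to -3.44, while 4, numbered 2648678, 2648679, 2648682 and 2648683, lay between -0.03 and 0.18. Of these, 2648683 is dim, with a control level of 4.83 (percentile 0.302 of the tested probesets), so that its small change says little. In CXCL12 at 6 hours 10 of 12 probesets had changes of 1.51 to 3.33, and probesets 3286622 and 3286623 of 0.22 ± 0.17 and -0.15 ± 0.13 (SE, 4 arrays per group). At 24 hours probeset 3286622 had a change of 0.99 ± 0.14, and 3286623 of 0.28 ± 0.23. In RET at 6 hours 29 of 32 probesets had changes of 0.76 to 2.57, and 3243849, 3243859 and 3243860 of 0.14, 0.08 and -0.25. These genes and probesets were singled out after their values were seen, with a limit of 0.5 on the size of a small change. Probesets that respond little in a gene that changed would give the same profile, so that these profiles alone do not show another promoter.

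**Figure D5:**
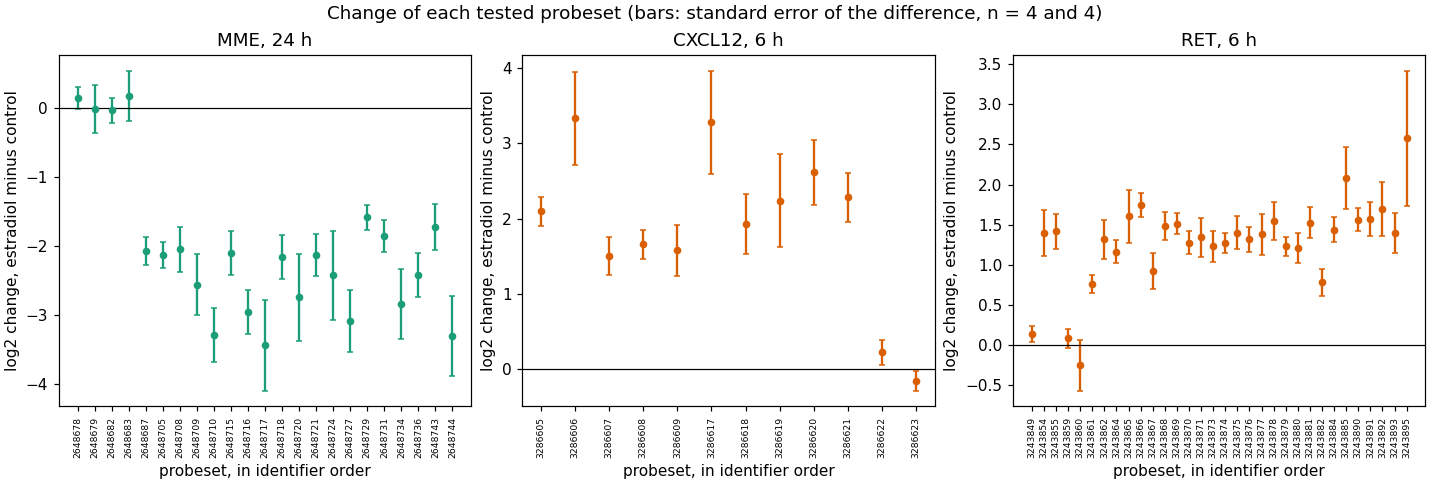
Log2 change with estradiol (vertical axis) of each tested probeset of MME at 24 hours and of CXCL12 and RET at 6 hours, in order of identifier (horizontal axis), with bars for the standard error of the difference of means of 4 and 4 arrays. In MME 4 probesets lie near 0 and 19 lie between -1.58 and -3.44.

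Relative usage, each probeset's log2 change minus that of the other probesets of its gene, was tested for 192316 probesets of 13466 genes. At 6 hours diffSplice called 112 probesets, 69 higher and 43 lower, in 101 genes, of which 5 had 2 or more called probesets; its Simes test called 86 genes. Apart from CXCL12 3286623 (relative change -2.22 ± 0.33, SE, adjusted p = 5.57e-06), the named rises were in EYA3 2403371 (2.67 ± 0.40), JAK2 3160904 (2.59 ± 0.37), RELT 3339900 (2.38 ± 0.31), ZFR 2852337 (2.08 ± 0.28) and SLC47A1 3713973 (2.07 ± 0.31), and the other named falls in POP1 3108677 (-2.59 ± 0.41), RAD1 2853006 (-2.44 ± 0.40), FCHO1 3824564 (-1.77 ± 0.27) and WDR86 3079675 (-1.65 ± 0.30). At 24 hours 519 probesets were called, 156 higher and 363 lower, in 457 genes, 44 of them with 2 or more, and the Simes test called 393 genes. The named rises were in MME 2648683 (2.30 ± 0.40), IGSF1 4021818 (2.12 ± 0.38), VAV1 3818560 (1.91 ± 0.32), CTPS2 4000908 (1.81 ± 0.28) and DOCK11 3988437 (1.79 ± 0.41), and the named falls in TAF9B 4013442 (-2.36 ± 0.38), PDZK1 2356446 (-2.08 ± 0.41), ADGRG2 4001683 (-1.99 ± 0.41), VRK2 2483481 (-1.95 ± 0.40) and RNF32 3033767 (-1.91 ± 0.36). At 24 hours the PDZK1, MME and DOCK11 probesets themselves moved by -0.10, 0.18 and 0.41, and at 6 hours CXCL12 3286623 by -0.15. The rest of these genes moved by 1.98, -2.12, -1.39 and 2.07. Each other named probeset moved more than the rest of its gene. All named probesets but those of CXCL12, WDR86 and DOCK11 lay at or below percentile 18.3 of the tested probesets by mean level. With its own variance the SE was larger for each but those of CXCL12 and DOCK11 (0.74 for TAF9B). A splicing index against the gene-level value kept 0 of the 18 named probesets it covered. Of the 8 fits without 1 array, the call of DOCK11 was lost in 4, of ADGRG2 and VRK2 in 2, and of RNF32, VAV1, RAD1 and WDR86 in 1.

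The groups did not overlap in relative value for 66 of the 112 and 282 of the 519 called probesets, and for 1.72% and 5.34% of all tested probesets. On a list of 30 genes with textbook alternative promoters, 25 genes with 414 probesets were tested: diffSplice called 0 probesets at 6 hours, and at 24 hours 7 probesets of BRCA1, ERBB2, GREB1, TGFB3 and TP63. That is 0% of the list against 0.0582% of all tested probesets at 6 hours, and 1.69% against 0.270% at 24 hours. Whether the list exceeds all probesets was not tested, and BRCA1, ERBB2, GREB1 and TGFB3 also changed at the gene level at 24 hours. None of the 7 passed with each probeset's own variance, where the only call at 24 hours was in MME. Among all probesets the count at an unadjusted p under 0.05 was 5493 at 6 hours and 11397 at 24 hours.

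Simulated arrays without any changed probeset gave 428 and 417 diffSplice calls at 6 and 24 hours, beside the 112 and 519 observed. The simulated probesets were drawn independently, and at 6 hours their count exceeded the observed one. The simulated counts therefore do not give the number of false calls in the data. The observed counts also moved with single arrays, to 178 and 72 at 6 hours without control replicate 2 and estradiol replicate 3, and at 24 hours to 206, 143 and 278 without control replicates 1, 3 and 4 and to 2180, 155 and 268 without estradiol replicates 1, 2 and 3. With each probeset's own variance, an alternative added after seeing the data, 2 probesets were called at 6 hours, CXCL12 3286623 (adjusted p = 0.0483) and RET 3243859 (-1.24 ± 0.16, adjusted p = 0.0483), and 1 at 24 hours, MME 2648678 (2.27 ± 0.27, adjusted p = 0.0276), while 7613 and 15246 had an unadjusted p under 0.05.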

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

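The tests of the called probesets were chosen only after the results were seen, and so was the test of array brightness behind another split of the 24 hour arrays; the other tests here were written before.

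Of 366 groups of 4 values tested for an array far from the other 3, 20 (5.46%) held one, and chance flags about 1 in 20 groups. In the 24 hour controls, replicate 2 was low in ATP10D (7.35), KLF6 (8.34), NCOA7 (6.64), PPP1R15A (7.88) and TMEM164 (7.24). There replicate 3 was high in EGLN3 (8.97) and replicate 1 in TFF1 (12.46). In the 6 hour controls, replicate 4 was high in EPHA4 (8.85), replicate 2 high in RET (8.02) and replicate 3 low in VTCN1 (5.23). With estradiol, replicate 1 at 24 hours was low in SLC7A5 (11.54). At 6 hours replicate 1 was high in GRHL3 (6.32) and low in TIAM1 (7.87), replicate 4 high in IL17RB (7.71) and RNF144B (7.16), and replicate 3 low in NOLC1 (8.62) and NPY1R (9.29). In relative value, CTPS2 4000908 was low in control 24 hour replicate 3 (-5.39), EYA3 2403371 high in control 6 hour replicate 1 (-1.24) and ADGRG2 4001683 low in estradiol 24 hour replicate 3 (-3.47).

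The estradiol effect differed between 24 and 6 hours, by limma's test of the difference, in H2BC14 (1.68), H1-4 (1.30), DHRS2 (0.93), TPM1 (-0.98), TIAM1 (-0.98) and SMOX (-0.77).

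Estradiol 24 hour replicate 1 lay near the 24 hour controls: its mean correlation with the other estradiol arrays was lower than that with the controls (difference -0.00506). A control array under an estradiol label is argued against by its score of 1.16 on the 214 genes called at 6 hours, where the controls average 0 (SD 0.0814) and the other estradiol arrays 1. A weaker response of these genes in that sample is argued against as well, since the lowest score among the other 3 was 0.936. After quantile normalization its score was 0.978 and the lowest of the others 0.967. Genes that respond only at 24 hours were not scored, so that a weaker late response stays open. Array brightness did not account for the lower correlation with the estradiol arrays, as the difference after quantile normalization was -0.00444 (SE 0.00129). What set this array apart stays open, and no other explanation was tested.

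Probesets called with a changed relative usage numbered 631 over both times. Probesets that respond little in genes that changed do not make up most of them, since 20.3% moved less than the rest of their gene. The 3 calls that passed with their own variance were such probesets, however. CXCL12 3286623 moved by -0.15 where the rest of its gene moved by 2.07, RET 3243859 by 0.08 and MME 2648678 by 0.15. For these 3 that explanation stays open. Dim probesets may account for many calls, with 64.7% in the lowest 25% of tested probesets by mean level. The use of one variance for all probesets of a gene may do so too, since 8.70% of the 23 calls with a relative change of 2 or more passed with their own variance, where 84% of simulated changes of 2 were recovered. Dim probesets and the shared variance remain open as technical explanations, and no biological one was tested.

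Genes lowered by estradiol at 24 hours had mostly risen in the controls: of 684 such clusters 661 were higher at 24 than at 6 hours, and 385 were called so, where 67.3 would be if the lists were independent, which they are not because both use the 24 hour controls. Sharing of these arrays is argued against as the whole cause: the covariance of the changes was -0.0688, against -0.0252 in simulations with shared controls alone, and with the controls divided into separate sets at least 92.2% of the lowered genes rose in the set not used to choose them, against 61.4% to 63.1% of all genes. Array brightness is argued against too, with at least 87.2% after quantile normalization against 43.8% to 46.3% of all genes. On arrays that did not choose the genes the median change from 6 to 24 hours was 0.26 with estradiol and 0.64 in the controls, but a smaller change with estradiol follows largely from choosing genes lower with estradiol at 24 hours, so that a rise over time held back by estradiol stays open. Why the control cells changed over these hours was not tested.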

How the results depend on the processing

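Of the alternatives below, the own-variance test, the fit without both arrays numbered 3, and quantile normalization for the lists and for the agreement of the times were chosen only after seeing the data. The cause was not tested for any change given here, except that fewer arrays or probesets were tested where arrays or probesets were left out.

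Genes changed at 6 hours (214) numbered 323 with array weights, 26 with only the 8 arrays of that time, 100 without both arrays numbered 3, and 83 to 244 without 1 array. At 24 hours (1072) they numbered 4280 with array weights and 589 to 2384 without 1 array. The difference between times (6) gave 10 with a replicate block, 43 after quantile normalization, 25 with median centring, 15 with array weights and 0 to 25 without 1 array. The replicate block ended the calls of DHRS2 and SMOX. The controls (2337) gave 1381 at 1.5-fold or more, 1131 after quantile normalization, 1302 with median centring and 921 to 2516 without 1 array.

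Lists at 6 hours (11) numbered 4 with an estimated correlation, 5 by fry and 7 to 13 without 1 array. At 24 hours (14) they numbered 5 with an estimated correlation, 12 by fry and 10 to 14 without 1 array. Probesets at 6 hours (112) numbered 260 with no filter on dim ones, 22 above the 50th percentile, 45 with only the 8 arrays of that time, 1 by the splicing index, 2 with their own variance and 72 to 178 without 1 array. At 24 hours (519) the same settings gave 866, 193, 1248, 21, 1 and 143 to 2180. The correlation of the times (0.179) was 0.349 without the dimmest 30% of clusters, 0.203 after quantile normalization and 0.0938 to 0.297 without 1 array. Its jackknife SD of 0.212 was computed from these fits without 1 array, so that their lying within it is no check. The SD is larger than the correlation itself, which it therefore does not set apart from 0.

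Each control array correlated best, in its deviation from the group mean, with the estradiol array of its own number in 4 of 4 cases at 6 hours (r = 0.219, 0.0156, 0.433 and 0.152) and 3 of 4 at 24 hours (r = 0.419, 0.299, -0.0157 and 0.160), where control replicate 3 matched estradiol replicate 1. This is a hint of pairing from the data, not the design, and a pair at each time was near 0, so that the numbers were not taken to pair the samples. A replicate block gave 207, 1152 and 2406 genes at 6 hours, at 24 hours and between the controls, 152 and 768 probesets, 11 and 14 lists, and the correlation at 0.179. That block ties arrays of the same number across both times, so that it is no check of pairing within a time, which was not fitted. Of 179 values of named genes 173 were kept with the block, 5 no longer passed and 1 newly passed.

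Directions turned only in values that were not called. MYC and ERBB2 were at 0.038 and 0.044 for the difference between times after quantile normalization. Between the controls MYC was at -0.22 after quantile normalization, -0.11 with median centring and from -0.10 to 0.16 without 1 array, and CCND1 at -0.094 and -0.049 with those scalings. CXCL12 was from -0.30 to 0.042 for the difference between times without 1 array.

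Of 2931 values of named genes under alternatives, 2660 kept direction and side of the threshold, 246 no longer passed, 17 newly passed and 8 turned. Of 325 values of lists 269 were kept and 56 no longer passed. Of 300 values of probesets 250 were kept and 50 no longer passed. Changes of 0.5 on the log2 scale were recovered in 20% of simulated genes. The position of called probesets within their genes was not run, since no positions were given.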

Other observations

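The comparison of the 24 with the 6 hour estradiol samples, its lists, the SE over arrays, the splits after quantile normalization and the test of histone genes were chosen only after the results were seen.

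With estradiol present, 330 clusters differed between 24 and 6 hours (limma), 232 higher and 98 lower, or 315 and 271 after quantile normalization. Of these, 176 were higher at 24 hours in the control cells too. Camera called the interferon, G1/S, G2/M, amino acid, estrogen-repressed and mesenchymal lists up and the estrogen-induced and luminal lists down. None of these calls held with an estimated correlation. Interferon-stimulated genes had 8 of 29 higher and 0 lower, with an adjusted p = 0.38 with an estimated correlation. Their mean change was 0.80 with estradiol and 1.03 in the controls, a difference of -0.23. The bound set beforehand used the SE over genes (0.061), which was wrong because these genes are correlated: the SE over arrays was 0.237, so that whether the rise was the same in both arms stays open. Tests of the difference for the list gave an adjusted p = 0.222 by camera, 0.792 with an estimated correlation and 0.43 by fry. By gene, 0 of the 29 passed limma's test of the difference and 1 had an unadjusted p under 0.05, and after quantile normalization the means were 0.76 and 0.86.

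The other replication-dependent histone genes were examined because H2BC14 and H1-4 were called for the difference between times. Of 58 listed genes 43 were measured, these called ones included. Without the called ones 41 remained, and 33 of the 41 had a larger estradiol effect at 24 than at 6 hours, with a mean difference of 0.62 (camera p = 0.0314 with an estimated correlation). At 24 hours 20 of the 41 rose with estradiol. This is consistent with the hypothesis that the histone genes moved as a group, which was found and tested on the same data.

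Taken over all 178850 pairs, probesets with neighbouring identifiers did not move together with estradiol beyond other splits of the arrays. A correlation over all genes cannot decide on blocks in a few genes, such as the 4 probesets of MME that stayed near 0 at 24 hours. At 6 hours the correlation of neighbours was -0.019, 26 of 35 splits gave one as high, and the highest other was 0.182. At 24 hours it was 0.0405, 4 of 35 splits gave one as high, and the highest other was 0.0647.

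Other splits of the same arrays were counted for each number of calls, the real split included. The real count stood far above every other split for the genes at 6 hours (214, highest other split 6, 1 of 35 as large), between the controls (2337, highest other 1, 1 of 35) and between the estradiol samples (330, highest other 2, 1 of 35). A share cannot fall below 1 of 35 here, and several counts were compared without adjustment, so that the share alone does not exclude chance. The lists at 24 hours had the highest count in the real split (14, 1 of 35). Another split gave 12, however, so that this count hardly sets the real grouping apart. For the difference between times (6) 2 of 100 drawn splits were as large, a share under 0.05. That share does not exclude chance, since another split called 53 genes and fits without 1 array called 0 to 25. Array brightness is argued against as the source of that split's calls, which numbered 166 after quantile normalization, where the real grouping called 43. Such a split points to a structure of the samples, and which structure was not tested. With the values as deposited chance cannot be excluded for the genes at 24 hours (1072, highest other 1273, 2 of 35). After quantile normalization the real count stood far above the others (1160, highest other 2). Nor can chance be excluded for the lists at 6 hours (11, highest other 12, 4 of 35). The same holds for the probesets at 6 hours (112, highest other 1858, 21 of 35) and at 24 hours (519, highest other 2421, 2 of 35), where splits with several times the real count point to a structure of the samples.

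The other 24 hour split, with 1273 genes, exchanged control replicate 2 and estradiol replicate 1, and parted arrays with medians of 6.57 to 6.65 from arrays with medians of 6.46 to 6.51. After quantile normalization the real split called 1160 genes and the highest other 2, so that array brightness may account for the calls of that other split.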
